A study of Homo sapiens with 34 samples.

How the data were processed

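RNA of 3 cell lines was measured by RNA-seq. Groups had DMSO, 72 h on an inhibitor, or 72 h on it and then 72 h without it. The sample annotation used here gave no hours for DMSO. Per the labels, A375 and MDA-MB-231 grew in DMEM and MCF7 in EMEM, both with serum. RNA with an integrity number above 7 was selected by oligo-dT, and strand-marked libraries were sequenced on a NovaSeq as 2 reads of 150 bases. The authors trimmed reads with cutadapt 1.9, aligned them to GRCh38 with STAR 2.7.9a and quantified them with RSEM 1.3.1, and deposited 1 table of TPM, transcript levels scaled to a common total. The annotation release, the strand setting and any filters were not given in the sources used here. The table held 62710 gene IDs, 42303 of them with a symbol, for 34 libraries. No library was left out, and the raw reads were not reprocessed. TPM keep no record of the number of reads, so the depth of each library, and the precision it gives, are unknown. Between 13062 and 14791 genes reached 1 TPM in a library, and 16.5% to 29.65% of TPM lay in mitochondrially encoded genes. Replicates of a group had Spearman correlations across genes of 0.963 to 0.982.

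Groups were taken from the labels, 2 libraries in each. Values were tested as log2(TPM + 1) in R 4.3.3 with limma 3.58.1, with a variance trend on the mean level. Libraries of 1 line were fitted together with 1 coefficient per group, over genes with at least 1 TPM in at least 2 libraries of that line. Tests were two-sided and p-values were adjusted by Benjamini and Hochberg, within each comparison for genes. An exact permutation of 2 against 2 libraries cannot give a p below 0.05, so the limma tests rest on a spread pooled over groups and genes. Each drug was compared with DMSO on drug and after withdrawal, and the withdrawn with the on-drug group. UNC1999 was compared with GSK126 and A485 with CCS1477 inside MDA-MB-231. The effect of CCS1477 in MCF7 minus that in MDA-MB-231 was tested as an interaction in 1 fit of both lines. The share of the change left was the change after withdrawal over the change on drug for each gene called on drug with an absolute log2 change of at least 1, given as a median over these genes.

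There were 26 gene lists with 488 members: NF-kB and cytokine, mitosis, DNA replication, ATF4, unfolded protein response, BET marker and polyadenylated histone, luminal and estrogen response, MYC and its targets, cholesterol, fatty acid synthesis, mesenchymal and matrix, epithelial, interferon, MHC class I, MHC class II, lysosome, hypoxia and glycolysis, mitochondrially encoded, AP-1 and ERK output, YAP and TEAD, p53, melanocyte, germline, developmental regulators, drug targets, and drug efflux and aldehyde dehydrogenases. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and also with an estimated correlation. List medians are of measured changes, and camera compares a list with all other genes, with p-values adjusted over all lists of the on-drug, the withdrawn or the difference comparisons. Named genes had a symbol, an adjusted p below 0.05, at least 5 TPM in the higher group, and both libraries of 1 group above both of the other. Of these the 8 with the largest change each way were named on drug and 5 otherwise. Up to 4 called members of a described list, or the 2 with the highest level where none was called, and called drug target genes were also named.

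The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a pseudocount of 0.1, no filter, median-ratio scaling of the libraries, a replicate block, 1 fit of all 34 libraries, leaving out each library in turn, split DMSO libraries, an absolute log2 change of at least 2 for shares, and the estimated correlation. Added after seeing the data were fits without mitochondrially encoded genes, without genes at least 10 times higher in another line, and without the 2 libraries richest in transcripts of another line. Markers of each line were also chosen after the data were seen: at least 50 TPM in every library of their line, and in the lowest library of the other line at most 0.5% of their mean. Stricter thresholds tried first left no markers.

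The code was tested on simulated data in which 200 genes per comparison were changed. It recovered 35% to 71% of them at a log2 change of 1 and 75% to 93% at 2, with 3 to 8 false calls, and a share left of 50% was recovered as 48.6% to 51%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.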

Results

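Inhibitors of BET bromodomains, of EZH2 and of the p300 and CBP acetyltransferases act on proteins that read or write chromatin marks. The series asked what 72 h of each inhibitor did to RNA levels in 3 cancer cell lines, and what remained 72 h after the drug was taken away. It held 34 libraries in 17 groups of 2: 6 from A375 melanoma cells, 6 from estrogen receptor positive MCF7 breast cancer cells and 22 from triple-negative MDA-MB-231 breast cancer cells. A375 received the BET inhibitor I-BET151 at 2 µM, and MCF7 the p300 and CBP bromodomain inhibitor CCS1477 at 10 µM. MDA-MB-231 received the BET inhibitor OTX-015 at 2 µM, the EZH2 inhibitors GSK126 and UNC1999 at 5 µM each, CCS1477 at 10 µM and the p300 and CBP acetyltransferase inhibitor A485 at 5 µM. Each line had 1 DMSO group, so the withdrawn groups had no control of the same time in culture. The labels did not say whether 2 replicates were separate cultures, so the p-values measured only the spread between these samples. Unless stated otherwise, changes are log2 fold changes of TPM + 1 against DMSO with their standard error (SE), and levels are mean TPM ± SD with n = 2. Genes were called by limma and lists by camera at an adjusted p below 0.05. Folds on this scale understated changes of genes with low levels.

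Some libraries held transcripts of a line other than their own. This was measured with the markers defined above, and genes moved by a drug can qualify. SAA1, SAA2, ANKRD1, TNC, TFF1, SPTSSB, DSCAM-AS1, FOXA1, RAB25 and H2BC21 are markers, so their shares below rest partly on themselves. A375 markers had a median of 19.2% of their A375 level in replicate 1 of the libraries withdrawn from A485, against 0.0415% in replicate 2. MCF7 markers had a median of 9.29% in OTX-015 replicate 2. They had medians of 1.84% and 1.77% in the MDA-MB-231 DMSO libraries and at most 0.927% in the other MDA-MB-231 libraries outside the OTX-015 arm. MDA-MB-231 markers in MCF7 had medians of 2.58% and 2.46% on CCS1477 and 2.75% in withdrawn replicate 2, against 0.376% and 0.48% in DMSO. A375 markers in MCF7 stood at 2.24% and 2.37% in DMSO and at 2.77% in withdrawn replicate 1. The A375 libraries held 1.64% to 1.9% of MCF7 markers except DMSO replicate 1, at 0.391%. The change that these shares alone would give was computed for the genes named and for called list members, and large shares of genes named below are given.

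**Figure D1:**
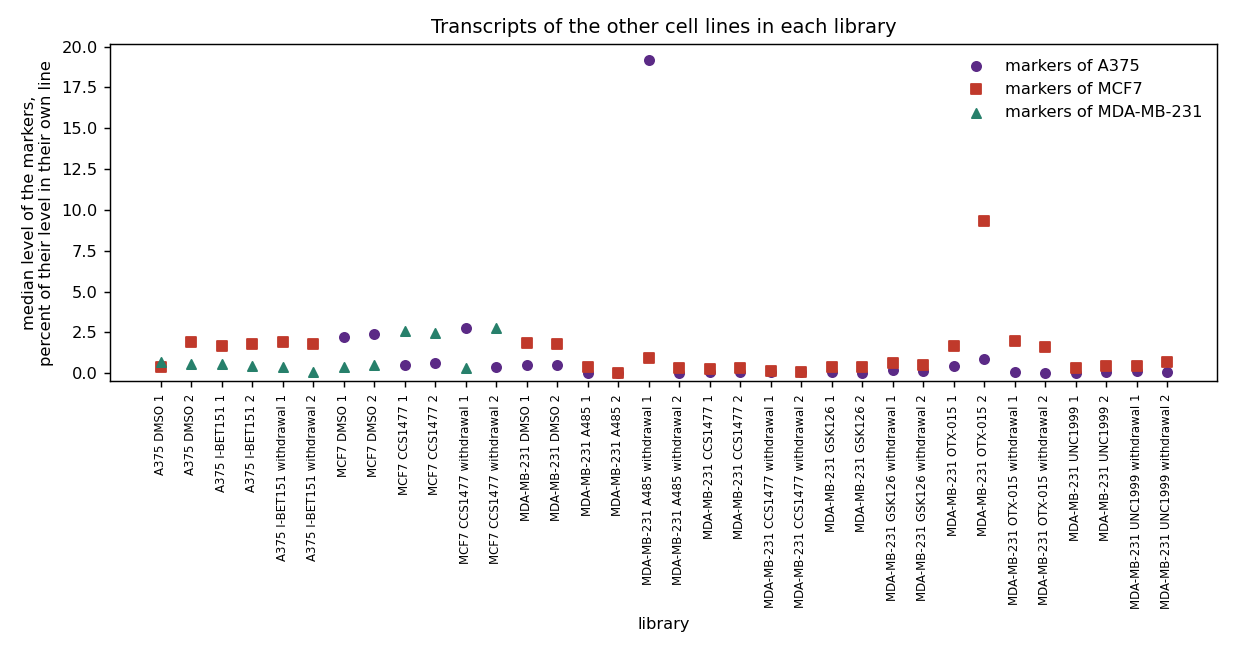
Median level of the markers of each other line in every library, as a percentage of their level in their own line. The A485 withdrawn replicate 1 library stood at 19.2% for A375 markers and the OTX-015 replicate 2 library at 9.29% for MCF7 markers.

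**Figure D2:**
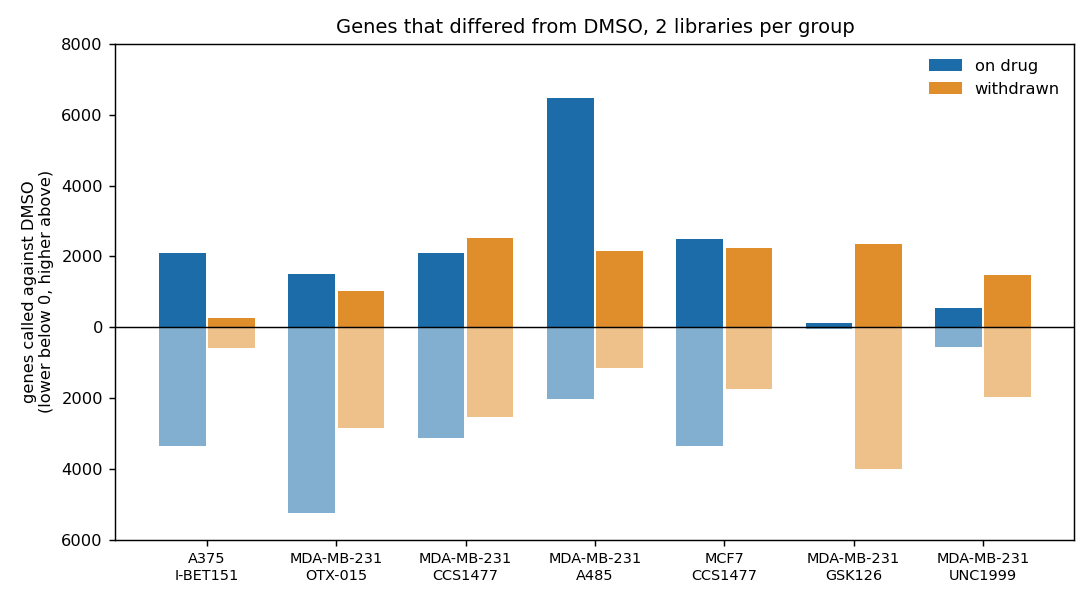
Genes called against DMSO in each arm, on drug and withdrawn. Bars above 0, in the darker shade, count genes that were higher, and bars below 0, in the lighter shade, count genes that were lower.

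**Figure D3:**
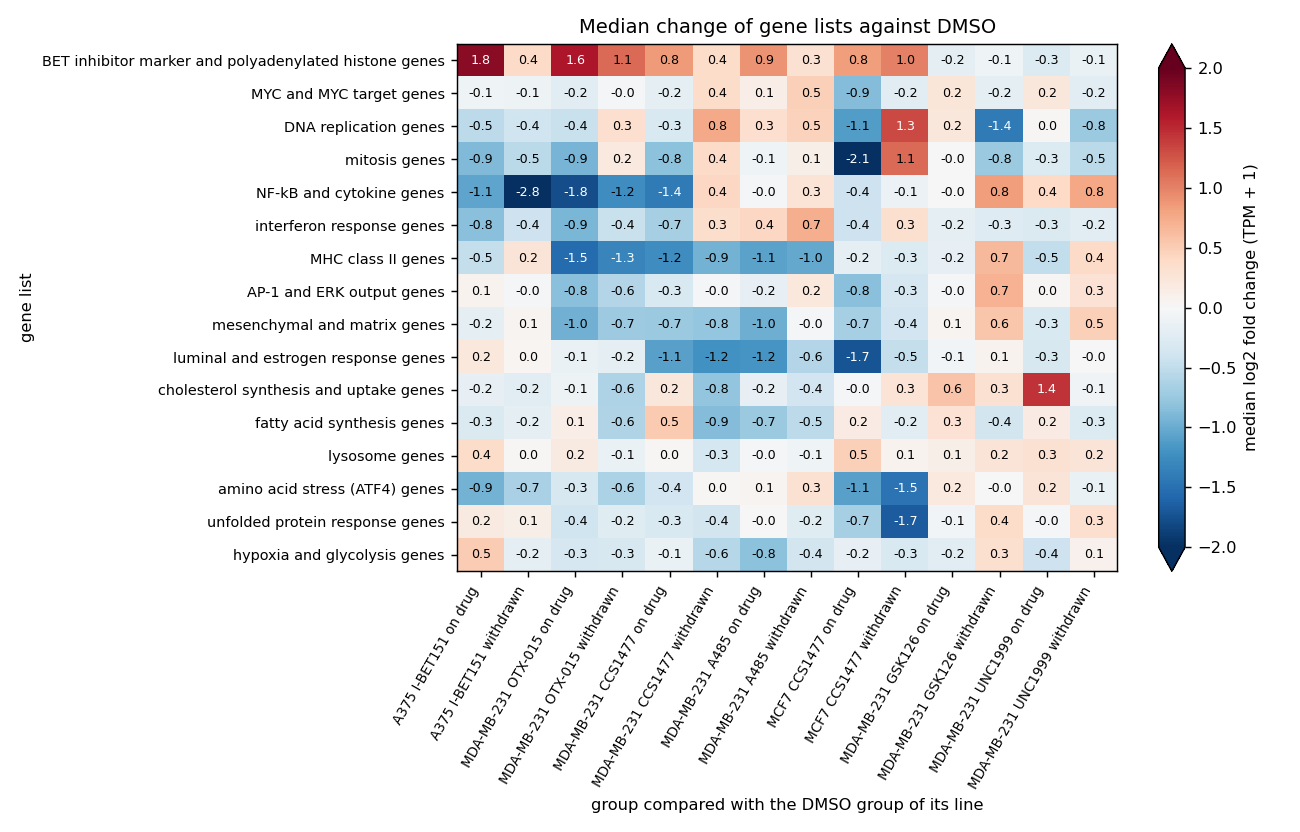
Median log2 fold change against DMSO of 16 gene lists in the 14 groups, as measured and before any scaling.

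What did 72 h of I-BET151 do to A375 cells? FST, which encodes the activin antagonist follistatin, fell to 1.79 ± 0.474 TPM against 102 ± 2.58 TPM (log2 -5.22, adjusted p = 6.08e-05). IL1A fell to 0.650 ± 0.255 TPM against 50.8 ± 1.79 TPM (log2 -4.98, adjusted p = 4.21e-05), followed by HAPLN1 (log2 -4.66, SE 0.21), CCL2 (-4.56, SE 0.19), CEMIP (-4.44, SE 0.11), PTGES (-4.02, SE 0.09), ART3 (-3.73, SE 0.27) and SERPINF1 (-3.71, SE 0.13). NF-kB and cytokine genes fell (1 up and 17 down of 20, 1 and 17 adjusted over the list alone, median -1.06), although IL11 rose (log2 2.03). BET inhibitor markers and polyadenylated histone genes rose (12 of 12, 12 adjusted over the list alone, median 1.80), with H2AC6 (log2 3.09, SE 0.15), H2BC5 (2.99, SE 0.25), H2BC21 (2.58, SE 0.28) and SAT1 (2.28, SE 0.05). Camera tests gave adjusted p = 7.74e-07 and 7.76e-10 (0.287 and 0.0936 with an estimated correlation). Histone genes H4C14 (log2 3.40, SE 0.11), H4C15 (3.22, SE 0.27), H4C12 (2.90, SE 0.41) and H2AC18 (2.75, SE 0.23) also rose, but their reads are shared with near-identical copies, so single histone assignments were uncertain. The host transcript MIR31HG (log2 2.87, SE 0.11) and the Wnt ligand WNT9A (log2 2.73, SE 0.16) rose too.

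Mitosis genes (19 of 20, 20 adjusted over the list alone, median -0.89) and DNA replication genes (15 of 23, 15 adjusted over the list alone, median -0.53) fell, as in KIF20A (log2 -1.37, SE 0.13) and MCM5 (-1.04, SE 0.09). Their camera tests gave adjusted p = 4.07e-09 and 2.13e-05 (0.403 and 0.403 with an estimated correlation). ATF4 genes of amino acid supply fell (0 up and 15 down of 19, 1 and 17 adjusted over the list alone, median -0.94), with CHAC1 (log2 -2.74, SE 0.15) and SLC7A11 (-1.94, SE 0.15). Camera gave adjusted p = 2.97e-07 (0.209 with an estimated correlation). Of the drug target genes, BRD2 (log2 0.74) and EP300 (0.56) rose and EZH2 (-0.51) and EED (-0.46) fell. Mitochondrially encoded genes were 19.61% of TPM against 17.23% in DMSO. Limma called 2096 genes up and 3341 down of 15208, a split that median-ratio scaling moved to 2832 and 2758. The total of 5437 became 3258 without I-BET151 replicate 1 and 3325 without replicate 2.

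How did A375 stand against DMSO 72 h after I-BET151? CCL2 fell to 0.525 ± 0.134 TPM against 115 ± 10.5 TPM (log2 -6.25, adjusted p = 6.97e-05), and the neutrophil chemokine CXCL8 to 20.2 ± 0.728 TPM against 1181 ± 107 TPM (log2 -5.80). Next came LCN2 (log2 -5.69, SE 0.19), CXCL1 (-5.29, SE 0.10) and CXCL2 (-4.97, SE 0.24). Genes of NF-kB and cytokines fell (18 of 20, 20 adjusted over the list alone, median -2.84), and so did ATF4 genes (12 of 19, 19 adjusted over the list alone, median -0.65), with CHAC1 (log2 -1.67, SE 0.15) and SLC7A5 (-1.35, SE 0.06). For these lists, camera gave adjusted p = 3.83e-28 and 1.61e-13 (0.0949 and 0.107 with an estimated correlation). Mitosis genes (13 of 20, 20 adjusted over the list alone, median -0.54) and replication genes (11 of 23, 18 adjusted over the list alone, median -0.40) stayed lower, as in UBE2C (log2 -0.68, SE 0.06) and E2F1 (-0.64, SE 0.09), with 6 of each called after scaling. Tested by camera, they had adjusted p = 2.27e-11 and 1.01e-08 (0.29 and 0.226 with an estimated correlation). The BET marker and histone list was still higher (3 of 12, 6 adjusted over the list alone, median 0.38). Its camera test gave adjusted p = 6.59e-06 (0.133 with an estimated correlation). EZH2 was still lower (log2 -0.58). The neuropeptide precursor VGF rose to 358 ± 11.8 TPM against 108 ± 23.2 TPM (log2 1.74), a call lost in the fit of all 34 libraries. EID2B (log2 1.54, SE 0.14) rose as well. The rises of MIR3677HG (log2 2.61, SE 0.38) and TCN1 (1.54, SE 0.24) were lost with no expression filter. The pseudogene RPS27P29, with 11.3 ± 2.16 TPM against a listed level of 0, may hold reads of its parent gene.

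Against DMSO 264 genes were up and 577 down, or 402 and 391 after scaling. The total of 841 fell to 149 and 225 without DMSO replicates 1 and 2, and to 103 and 117 without withdrawn replicates 1 and 2. It was 425 with no expression filter and 421 with a replicate block. Compared directly, 2472 genes were higher and 2269 lower after withdrawal than on drug. That total of 4741 became 2557 and 2609 without on-drug replicates 1 and 2, and 2528 and 2751 without withdrawn replicates 1 and 2. Of 1344 genes called at 2-fold or more on drug, 16% were still called the same way, 81.2% had moved back by a called amount, and the median share left was 21%.

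What did 72 h of CCS1477 do to MCF7, a luminal, estrogen-driven line? The imprinted transcript H19 fell to 0.145 ± 0.00707 TPM against 189 ± 21.0 TPM (log2 -7.37, adjusted p = 1.94e-05), and S100A14 to 5.53 ± 0.0566 TPM against 409.9 ± 38.0 TPM (log2 -5.97, adjusted p = 2e-05). S100A8 went to a listed level of 0 against 38.9 ± 0.156 TPM, and KCNE4 (log2 -5.10, SE 0.20), AKR1C2 (-5.03, SE 0.11), S100A9 (-4.83, SE 0.38) and MGP (-4.81, SE 0.23) fell. The pseudogene RPS27P2 was listed at 0 on drug. Luminal and estrogen response genes fell (2 up and 20 down of 22, 2 and 20 adjusted over the list alone, median -1.73), led by SPDEF (log2 -4.72, SE 0.18), PDZK1 (-4.43, SE 0.23) and AREG (-4.00, SE 0.12). Mitosis genes fell (20 of 20, 20 adjusted over the list alone, median -2.09), with AURKB (log2 -2.74, SE 0.21), KIF20A (-2.63, SE 0.19) and CDC20 (-2.54, SE 0.13). In that order, camera gave adjusted p = 8.12e-10 and 9.79e-13 (0.39 and 0.277 with an estimated correlation). DNA replication genes (22 of 23, 23 adjusted over the list alone, median -1.11) and MYC and its targets (18 of 24, 21 adjusted over the list alone, median -0.86) fell, as in RRM2 (log2 -2.13, SE 0.15) and MYC (-1.18, SE 0.11). The 2 tests gave adjusted p = 4.29e-09 and 3.55e-07 (0.364 and 0.403 with an estimated correlation). The ATF4 list (14 of 19, 15 adjusted over the list alone, median -1.08) and the unfolded protein response (12 of 15, 12 adjusted over the list alone, median -0.67) fell too, as in TRIB3 (log2 -2.49, SE 0.17) and SDF2L1 (-1.77, SE 0.15). Both camera tests gave adjusted p = 2.27e-06 and 3.27e-05 (0.492 and 0.492 with an estimated correlation).

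Among the rises were the histone genes H2AC11 (log2 3.49, SE 0.22) and H4C5 (3.28, SE 0.53) and the small RNA gene RPPH1 (3.10, SE 0.39), the pseudogene H2BC20P (3.65, SE 0.51), and H3C14 and SRP9P1, both listed at 0 in DMSO. Reads of these genes can be shared with copies, so the assignments were uncertain. The BET marker and histone list rose (8 up and 3 down of 12, 8 and 4 adjusted over the list alone, median 0.83), with SERPINI1 (log2 2.17, SE 0.25) and HEXIM1 (1.62, SE 0.11). The camera test gave adjusted p = 0.00745 (0.492 with an estimated correlation). The acute phase gene SAA1 (log2 3.40, SE 1.04) and the cystatin CST1 (log2 3.35, SE 0.66) rose, but both are abundant in MDA-MB-231. MDA-MB-231 shares were 87% of the SAA1 change and 122% of the CST1 change, and the SAA1 call was lost with a pseudocount of 0.1. BRD2 rose (log2 1.19) and EZH2 fell (-0.50). Mitochondrially encoded genes were 29.64% of TPM, against 25.31% and 17.64% in the DMSO libraries. Limma called 2502 genes up and 3348 down of 15251. The total of 5850 became 3046 without CCS1477 replicate 1 and 3060 without replicate 2.

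How did MCF7 stand 72 h after CCS1477? Mitosis genes, lower on drug, stood above DMSO (20 of 20, 20 adjusted over the list alone, median 1.13), with MKI67 (log2 1.44, SE 0.18), PLK1 (1.40, SE 0.20) and CDK1 (1.37, SE 0.12). So did DNA replication genes (21 of 23, 22 adjusted over the list alone, median 1.32), with TYMS (log2 1.97, SE 0.18) and E2F1 (1.64, SE 0.19). Camera, in that order, gave adjusted p = 7.38e-11 and 3.89e-12 (0.229 and 0.229 with an estimated correlation). Endoplasmic reticulum chaperones of the unfolded protein response fell (14 of 15, 14 adjusted over the list alone, median -1.67), with HSPA5 (log2 -2.39, SE 0.14), DNAJB9 (-2.20, SE 0.11) and SDF2L1 (-2.13, SE 0.15). The ATF4 list also fell (1 up and 15 down of 19, 1 and 17 adjusted over the list alone, median -1.48), where the cystine and leucine carriers SLC7A11 (log2 -3.31, SE 0.20) and SLC7A5 (-2.97, SE 0.13) lost most. The pair of tests gave adjusted p = 1.11e-13 and 1.44e-11 (0.245 and 0.298 with an estimated correlation). Luminal genes stayed low in part (1 up and 12 down of 22, 2 and 13 adjusted over the list alone, median -0.47), as in SPDEF (log2 -3.23, SE 0.18), PDZK1 (-3.18, SE 0.23) and STC2 (-3.10, SE 0.10), and the BET marker and histone list stayed high (8 up and 1 down of 12, 9 and 2 adjusted over the list alone, median 1.01). Camera tests gave adjusted p = 4.15e-06 and 0.000967 (0.364 and 0.364 with an estimated correlation). Lasting losses were H19 (log2 -5.72, SE 0.22), S100A8 (-4.80, SE 0.33), S100A14 (-4.49, SE 0.19) and S100A9 (-4.45, SE 0.38). CYP1A1, an aryl hydrocarbon receptor target, fell to 1.11 ± 0.643 TPM against 37.4 ± 0.700 TPM (log2 -4.22, adjusted p = 0.000226). Drug efflux genes fell (4 of 10, 4 adjusted over the list alone, median -0.51), mainly ABCC3 (log2 -3.45, SE 0.21). Tested by camera, it had adjusted p = 0.00984 (0.245 with an estimated correlation).

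Higher transcripts were CNIH2 (log2 2.69, SE 0.26), the readthrough CENPS-CORT (3.14, SE 0.31), and RMRP, SRP9P1 and RN7SL535P, all 3 listed at 0 in DMSO. All but CNIH2 can share reads with copies or neighbouring genes, so they were uncertain. RMRP lost its call with scaling, with no filter and with a replicate block. SUZ12 (log2 0.66), BRD2 (0.69), EED (0.57) and EZH2 (0.48) were higher than in DMSO. Mitochondrially encoded genes were 22.86% of TPM. Limma called 2239 genes up and 1730 down, or 2239 and 2370 after scaling. The total of 3969 became 2394 and 1791 without withdrawn replicates 1 and 2, and 5954 in the fit of all 34 libraries. Against the on-drug group 2565 were higher and 1224 lower, or 2362 and 2088 after scaling. That total of 3789 became 1350 and 1280 without on-drug replicates 1 and 2, 1772 and 2053 without withdrawn replicates 1 and 2, 2337 with no filter and 5827 in the 34-library fit. Of 2236 genes changed 2-fold or more on drug, 53.7% were still called the same way, 48.4% had moved back and the median share left was 53.9%.

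What did 72 h of A485 do to MDA-MB-231? Scaling moved the all-gene median by -0.311, so list medians here are relative to the measured all-gene median of 0.311, and single genes are as measured. The hyaluronidase CEMIP fell to 1.79 ± 2.04 TPM against 192 ± 1.06 TPM (log2 -6.33, adjusted p = 5.79e-09), with KRT80 (log2 -5.34, SE 0.11), CST1 (-5.31, SE 0.18), ANXA8 (-5.27, SE 0.27), CST7 (-5.09, SE 0.16) and KRT81 (-4.90, SE 0.10). SPINK4 went to a listed level of 0 against 123 ± 0.120 TPM, and the trefoil factor TFF1 to a listed level of 0 against 29.1 ± 7.52 TPM. TFF1 is an MCF7 gene, with an MCF7 share of 292%. Mesenchymal and matrix genes fell (2 up and 11 down of 19, 2 and 11 adjusted over the list alone, median -1.29), with TGFBI (log2 -4.02, SE 0.18), FN1 (-3.24, SE 0.12), SNAI2 (-2.90, SE 0.14) and LOX (-2.64, SE 0.22). Camera called them at adjusted p = 1.48e-09 (0.0246 with an estimated correlation). Hypoxia and glycolysis genes (1 up and 13 down of 18, 1 and 13 adjusted over the list alone, median -1.13) and MHC class II genes (8 of 12, 8 adjusted over the list alone, median -1.39) fell, as in EGLN3 (log2 -2.40, SE 0.19), HLA-DRA (-3.30, SE 0.39) and its regulator CIITA (-2.86, SE 0.25). Their camera tests gave adjusted p = 6.49e-08 and 6.46e-07 (0.273 and 0.209 with an estimated correlation). Fatty acid synthesis genes (1 up and 8 down of 11, 2 and 8 adjusted over the list alone, median -1.05) and luminal genes (9 of 16, 10 adjusted over the list alone, median -1.49) fell too, as in SCD (log2 -3.11, SE 0.12), SREBF1 (-1.75, SE 0.13) and CA12 (-4.13, SE 0.31). For these lists, camera gave adjusted p = 5.93e-05 and 5.77e-08 (0.0936 and 0.209 with an estimated correlation). MCF7 shares, too high for TFF1 at 292%, were 65.3% for GATA3, 108% for FOXA1 and 26.6% for NRIP1. With TFF1 these genes are 4 of the 9 luminal calls. Mitochondrially encoded genes, 20.43% of TPM against 25.49% in DMSO, fell (8 of 13, 8 adjusted over the list alone, median -0.65). For that list, camera gave adjusted p = 5.63e-06 (0.277 with an estimated correlation).

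The immediate early gene EGR1 rose to 115 ± 15.0 TPM against 2.81 ± 0.339 TPM (log2 4.92, adjusted p = 3.73e-07), while its AP-1 list was called lower (5 up and 9 down of 19, 5 and 9 adjusted over the list alone, median -0.48). This test gave adjusted p = 0.0161 (0.513 with an estimated correlation). Also higher were RNF227 (log2 3.39, SE 0.30), RBP7 (2.78, SE 0.45) and EXOG (2.79, SE 0.84), and GCH1 at 28.1 ± 2.30 TPM against 3.48 ± 0.318 TPM. KRT8P51, NDUFA4P1 and MTND4LP30, listed at 0 in DMSO, are pseudogenes that share reads, and NDUFA4P1 lost its call with scaling. CREBBP (log2 0.86), EP300 (0.84), EED (0.77), BRD2 (0.68), SUZ12 (0.63), BRD4 (0.61) and BRD3 (0.47) rose, and 2 of these 7 calls were left after scaling. Of 16329 genes, 6477 were up and 2036 down, and after scaling 2578 and 3244, from 76.1% up to 44.3%.

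How did MDA-MB-231 stand against DMSO 72 h after A485? Interferon response genes rose (15 up and 0 down of 21, 17 and 1 adjusted over the list alone, median 0.72), with ISG15 (log2 1.95, SE 0.12), OASL (1.89, SE 0.13) and RSAD2 (1.61, SE 0.19). Camera gave adjusted p = 1.88e-08 (0.0743 with an estimated correlation). The cytokine IL24 rose to 73.7 ± 0.615 TPM against 8.80 ± 0.891 TPM (log2 2.93, adjusted p = 1.14e-06), as did KRTAP2-3 (log2 2.68, SE 0.33), PCBP1-AS1 (2.26, SE 0.26) and CSF3 (2.25, SE 0.29). MYC and its targets (14 of 24, 16 adjusted over the list alone, median 0.48) and DNA replication genes (10 of 23, 18 adjusted over the list alone, median 0.46) rose, as in BOP1 (log2 0.76, SE 0.10) and RRM2 (1.01, SE 0.21). Tested by camera, they had adjusted p = 1.9e-07 and 1.07e-05 (0.196 and 0.321 with an estimated correlation). Other-line shares, displaced RNA not subtracted, were 28.7% to 61.1% in 11 MYC list members and 29.9% to 35% in MCM2, PCNA and MCM7. Both list calls held without the 2 libraries richest in other-line transcripts. Cholesterol genes (1 up and 12 down of 24, 1 and 13 adjusted over the list alone, median -0.38) and MHC class II genes (0 up and 7 down of 12, 1 and 8 adjusted over the list alone, median -1.02) fell, with PCSK9 (log2 -1.63, SE 0.19) and HLA-DPB1 (-2.02, SE 0.26). In that order, camera gave adjusted p = 1.01e-08 and 5.17e-07 (0.104 and 0.15 with an estimated correlation). The endothelial lipase LIPG fell to 2.12 ± 0.955 TPM against 28.8 ± 0.332 TPM (log2 -3.29). TGFB2-OT1 (log2 -3.28, SE 0.63) and TFF1 (-3.50, SE 0.84) fell too, TFF1 with an other-line share of 199%. The pseudogenes RN7SL657P and RPL32P24, listed at 0 after A485, and the histone gene H4C12, listed at 0 in DMSO, can share reads. The H4C12 call was lost without the 2 libraries richest in other-line transcripts. BRD2 was higher (log2 0.21), a call lost with scaling, and its other-line share was 28.8%. Mitochondrially encoded genes were 20.85% of TPM against 25.49% in DMSO.

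Limma called 2157 genes up and 1151 down, or 1372 and 1509 after scaling. The total of 3308 became 2026 and 1701 without DMSO replicates 1 and 2 and 2050 without withdrawn replicate 1, the library with A375 transcripts. Against the on-drug group 1809 genes were higher and 5322 lower. Scaling moved that all-gene median by 0.234 and the split to 2973 and 2162. Of 2029 genes changed 2-fold or more on drug, 36.6% were still called the same way, 79.5% had moved back and the median share left was 29.6%.

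What did CCS1477 do to MDA-MB-231 in 72 h? The long noncoding RNA UCA1 rose to 2310 ± 188 TPM against 137 ± 0.198 TPM (log2 4.06, adjusted p = 4.87e-09). The metallothionein MT1A (log2 3.20, SE 0.28), the neuronal tubulin TUBB3 (2.96, SE 0.34), ZNF114 (2.94, SE 0.22) and FAM89B (2.86, SE 0.20) rose too, as did STIM2-AS1, listed at 0 in DMSO. NF-kB and cytokine genes fell (2 up and 15 down of 22, 2 and 16 adjusted over the list alone, median -1.41), with CSF2 (log2 -3.24, SE 0.21), IL6 (-3.11, SE 0.18), CXCL1 (-2.50, SE 0.07) and CXCL8 (-2.50, SE 0.12). Camera called them at adjusted p = 4.9e-09 (0.0214 with an estimated correlation). Mitosis genes (17 of 20, 18 adjusted over the list alone, median -0.82) and interferon response genes (1 up and 10 down of 21, 3 and 11 adjusted over the list alone, median -0.67) fell, as in CENPF (log2 -1.42, SE 0.23), CCNA2 (-1.15, SE 0.13) and OASL (-2.29, SE 0.13). The 2 tests gave adjusted p = 1e-08 and 0.00674 (0.297 and 0.329 with an estimated correlation). The BET marker and histone list (9 of 12, 9 adjusted over the list alone, median 0.85) and fatty acid synthesis genes (8 up and 1 down of 11, 8 and 1 adjusted over the list alone, median 0.52) rose, with H2BC5 (log2 2.46, SE 0.18), H2AC6 (2.21, SE 0.28) and FASN (1.47, SE 0.13). Both camera tests gave adjusted p = 5.63e-07 and 0.000186 (0.0619 and 0.108 with an estimated correlation). MHC class I genes were lower (10 of 15, 12 adjusted over the list alone, median -0.35), with ERAP1 (log2 -1.20, SE 0.18). Its camera test gave adjusted p = 0.00036 (0.329 with an estimated correlation). ADGRF1, an adhesion receptor, fell to 1.53 ± 0.438 TPM against 30.1 ± 0.191 TPM (log2 -3.63), with MANCR (log2 -3.43, SE 0.24), PDZK1IP1 (-3.42, SE 0.18), EVI2A (-3.37, SE 0.29) and CEMIP (-3.33, SE 0.36). TFF1 (log2 -4.56, SE 0.84) and SPTSSB (log2 -3.42, SE 0.70) fell as well, with MCF7 shares of 278% and 156%. The pseudogene RPS28P4 and the readthrough RPL36A-HNRNPH2, listed at 0 in DMSO, and the small RNA gene RMRP (log2 -4.11, SE 1.33) were uncertain, and all 3 lost their calls with no filter. BRD2 rose (log2 1.10) and EZH2 fell (-0.60). Limma called 2098 genes up and 3137 down.

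What followed CCS1477 in MDA-MB-231? Lipid synthesis turned down, while division, NF-kB and interferon lists, lower on drug, turned up. The desaturase SCD fell to 37.1 ± 0.891 TPM against 483 ± 4.55 TPM (log2 -3.67, adjusted p = 2.5e-10) and LIPG to 0.745 ± 0.247 TPM against 28.8 ± 0.332 TPM (log2 -4.10). Cholesterol genes (1 up and 20 down of 24, 1 and 20 adjusted over the list alone, median -0.79) and fatty acid synthesis genes (1 up and 8 down of 11, 1 and 9 adjusted over the list alone, median -0.86) fell, with INSIG1 (log2 -2.85, SE 0.15) and SREBF1 (-2.19, SE 0.13). Camera, in that order, gave adjusted p = 1.7e-10 and 1.19e-06 (0.0896 and 0.0743 with an estimated correlation). DNA replication genes (20 of 23, 22 adjusted over the list alone, median 0.75) and mitosis genes (11 up and 0 down of 20, 11 and 1 adjusted over the list alone, median 0.39) were above DMSO, as in RRM2 (log2 1.54, SE 0.21) and AURKB (0.78, SE 0.13). The pair of tests gave adjusted p = 3.89e-12 and 0.000264 (0.15 and 0.387 with an estimated correlation). Genes of NF-kB and cytokines (10 up and 2 down of 22, 12 and 2 adjusted over the list alone, median 0.41) and interferon genes (8 up and 1 down of 21, 8 and 1 adjusted over the list alone, median 0.35) were higher, with IL11 (log2 2.46, SE 0.21), CSF2 (1.94, SE 0.21) and ISG15 (2.15, SE 0.12). Camera tests gave adjusted p = 0.000352 and 0.000236 (0.133 and 0.15 with an estimated correlation). ANGPTL4 (log2 3.20, SE 0.25) rose with LTB (2.53, SE 0.30) and UCA1 (2.34, SE 0.19). TGFB2-OT1 (log2 -3.61, SE 0.63) fell, while TFF1 and SPTSSB, listed at 0 after withdrawal, had MCF7 shares of 309% and 175%. EED (log2 0.56), EZH2 (0.41) and BRD2 (0.25) were higher. Limma called 2533 genes up and 2541 down, and the total of 5074 became 3208 without withdrawn replicate 1. Against the on-drug group 2876 were higher and 1813 lower, and that total of 4689 became 3117 without on-drug replicate 2 and 3028 without withdrawn replicate 1. Of 1212 genes changed 2-fold or more on drug, 58.7% were still called the same way, 50.8% had moved back and the median share left was 54.7%, or 35.3% for the 345 that rose and 65.1% for the 867 that fell.

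What did GSK126 do to MDA-MB-231 in 72 h? Few genes were called. Cholesterol synthesis and uptake genes rose (14 of 24, 21 adjusted over the list alone, median 0.57), with PCSK9 (log2 1.16, SE 0.19), DHCR7 (1.07, SE 0.12), HMGCS1 (0.94, SE 0.16) and ACAT2 (0.84, SE 0.07). Camera called them at adjusted p = 8.55e-28 (0.00851 with an estimated correlation). DHCR7, the last enzyme of the cholesterol pathway, rose to 169 ± 7.95 TPM against 80.0 ± 1.85 TPM (adjusted p = 0.00101). The assembly factor NDUFAF4 (log2 1.38, SE 0.23), RNASE1 (1.09, SE 0.19), PRSS2 (1.06, SE 0.20), MCOLN2 (0.99, SE 0.19) and NCF2 (0.98, SE 0.20) rose too. Of the genes that fell, TFF1 (log2 -4.55, SE 0.84) and SPTSSB (log2 -3.35, SE 0.70), and DSCAM-AS1, listed at 0 on drug, are MCF7 genes. Their MCF7 shares were 265%, 149% and 190%. For H2BC21 (log2 -1.75, SE 0.37) and H4C14 (-2.31, SE 0.51) the shares were 77% and 56%. PTPN4 (log2 -1.49, SE 0.33) fell too. FTH1P8 (log2 1.74), and FGF7P5 and RN7SL657P, listed at 0 on drug, are pseudogenes that may share reads. PCSK9, TFF1, RNASE1, PRSS2, PTPN4, RN7SL657P and FGF7P5 lost their calls with a pseudocount of 0.1, NCF2, SPTSSB, DSCAM-AS1, H2BC21 and H4C14 with no filter, and MCOLN2 in the fit of all 34 libraries. No drug target gene was called. Limma called 126 genes up and 46 down. The total of 172 became 22 and 12 without DMSO replicates 1 and 2, 18 and 15 without GSK126 replicates 1 and 2, and 399 without the 2 libraries richest in other-line transcripts.

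What stood apart from DMSO 72 h after GSK126? Far more genes were called than on drug. Scaling moved the all-gene median by 0.116, so list medians are relative to the measured median of -0.112. DNA replication genes (23 of 23, 23 adjusted over the list alone, median -1.30) and mitosis genes (19 of 20, 19 adjusted over the list alone, median -0.64) fell, with DHFR (log2 -1.97, SE 0.12) and KIF11 (-1.46, SE 0.14). Their camera tests gave adjusted p = 5.54e-15 and 4.8e-08 (0.123 and 0.245 with an estimated correlation). Mitochondrially encoded genes, 18.33% of TPM against 25.49% in DMSO, fell too (12 of 13, 12 adjusted over the list alone, median -0.45). The camera test gave adjusted p = 3.42e-06 (0.196 with an estimated correlation). NF-kB and cytokine genes (16 up and 3 down of 22, 17 and 3 adjusted over the list alone, median 0.94) and AP-1 and ERK output (11 of 19, 11 adjusted over the list alone, median 0.81) rose, with IL1B (log2 3.08, SE 0.18), CCL20 (2.84, SE 0.31) and EGR1 (3.57, SE 0.43). For these lists, camera gave adjusted p = 1.56e-08 and 4.68e-07 (0.0563 and 0.177 with an estimated correlation). Matrix genes (11 up and 1 down of 19, 11 and 1 adjusted over the list alone, median 0.66) and the unfolded protein response (10 of 15, 11 adjusted over the list alone, median 0.49) rose, with FN1 (log2 2.61, SE 0.12) and HSPA5 (0.63, SE 0.10). Tested by camera, they had adjusted p = 6.15e-06 and 1.98e-05 (0.0949 and 0.144 with an estimated correlation). CHI3L2, a secreted chitinase-like protein, rose to 102 ± 16.8 TPM against 5.09 ± 1.66 TPM (log2 4.09, adjusted p = 1.02e-07). p53 targets (6 up and 2 down of 19, 6 and 2 adjusted over the list alone, median 0.48) and developmental regulators (3 of 9, 3 adjusted over the list alone, median 0.56) were called higher, with CDKN1A (log2 2.01, SE 0.17) and HAND1 (1.03, SE 0.23). In that order, camera gave adjusted p = 0.0372 and 0.0207 (0.364 and 0.197 with an estimated correlation), and the developmental call was lost with no filter. NPIPA7 (log2 -2.76, SE 0.45) and SPTSSB (log2 -3.40, SE 0.70) fell, and DSCAM-AS1 and the pseudogenes RN7SL657P and FGF7P5 were listed at 0. The MCF7 shares were 128% of the change of SPTSSB and 164% of DSCAM-AS1. RPL36A-HNRNPH2, H4C12 and CKS1BP1, listed at 0 in DMSO, can share reads with other genes. SUZ12 (log2 -1.10), CREBBP (-0.97), EZH2 (-0.89), EP300 (-0.70), BRD3 (-0.45) and EED (-0.37) fell, but after scaling 3 drug target genes were lower and 1 higher.

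Limma called 2350 genes up and 4001 down, or 3301 and 2720 after scaling. The total of 6351 became 4153 without DMSO replicate 2. Against the on-drug group 2190 were higher and 3905 lower. Scaling moved that all-gene median by 0.109 and the split to 3234 and 2640. Of 31 genes changed 2-fold or more on drug, 64.5% were still called the same way, 35.5% had moved back and the median share left was 81.6%, or 44% for the 15 that rose and 92.9% for the 16 that fell. It was 33.8% and 42% without on-drug replicates 1 and 2. The falls include the MCF7 genes TFF1, SPTSSB and DSCAM-AS1, and both changes use the same DMSO libraries. Of 1302 genes changed 2-fold or more after withdrawal, 1267 had not been called on drug.

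What did OTX-015 do to MDA-MB-231 in 72 h? Scaling moved the all-gene median by 0.219, so list medians are relative to the measured median of -0.219. Cytokine RNA fell. The growth factor gene CSF2 fell to 0.750 ± 0.580 TPM against 84.9 ± 4.39 TPM (log2 -5.66, adjusted p = 3.03e-10), and IL6 to 4.96 ± 1.17 TPM against 150.3 ± 13.9 TPM (log2 -4.68). The NF-kB and cytokine genes fell (1 up and 17 down of 22, 1 and 17 adjusted over the list alone, median -1.55), while BET markers and polyadenylated histone genes rose (9 of 12, 10 adjusted over the list alone, median 1.84), with H2BC4 (log2 3.83, SE 0.57), H2AC6 (3.51, SE 0.28), H2BC5 (3.48, SE 0.18) and H1-2 (3.29, SE 0.17). The 2 tests gave adjusted p = 1.5e-09 and 1.78e-10 (0.0214 and 0.0214 with an estimated correlation), so both calls held. Also lower were CEMIP (log2 -4.61, SE 0.36), ANXA8 (-4.21, SE 0.27), IL1B (-4.12, SE 0.18), ADGRF1 (-4.08, SE 0.17), NNMT (-3.93, SE 0.14) and PLEKHS1 (-3.80, SE 0.22). UCA1 (log2 3.65, SE 0.19) and CYSRT1 (log2 3.37, SE 0.21) rose, and so did the histone gene H4C8 (log2 3.49, SE 0.41), at uncertain assignment. H4C12 and the pseudogene FAUP4 were listed at 0 in DMSO, and FAUP4 lost its call with no filter. Mitosis genes (20 of 20, 20 adjusted over the list alone, median -0.71) and MHC class II genes (9 of 12, 9 adjusted over the list alone, median -1.32) fell, with CENPF (log2 -1.75, SE 0.23) and CTSS (-3.11, SE 0.20). Both camera tests gave adjusted p = 2.64e-07 and 0.00111 (0.346 and 0.403 with an estimated correlation). Epithelial genes were called higher (7 up and 2 down of 19, 7 and 2 adjusted over the list alone, median 0.58), with KRT8 (log2 1.44, SE 0.11) and KRT18 (1.26, SE 0.11). Tested by camera, it had adjusted p = 0.00182 (0.532 with an estimated correlation), a call lost without the 2 libraries richest in other-line transcripts. MCF7 shares were 118% for ESRP1, 90% for RAB25, 76.1% for MAL2, 27% for KRT8 and 25.3% for KRT18. BRD2 (log2 1.28) and EZH1 (0.33) rose, and EZH2 (-0.47) and BRD4 (-0.46) fell, but after scaling no drug target gene was called lower. Mitochondrially encoded genes were 27.7% of TPM against 25.49% in DMSO. Limma called 1493 genes up and 5240 down, and 3079 and 3231 after scaling.

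How did MDA-MB-231 stand against DMSO 72 h after OTX-015? Scaling moved the all-gene median by 0.112, so list medians are relative to the measured median of -0.112. Inflammatory RNA stayed low. IL1B (log2 -3.44, SE 0.18), LCN2 (-3.35, SE 0.12), IFITM1 (-3.32, SE 0.25) and the semaphorin SEMA6B (-3.47, SE 0.14) fell, and NF-kB and cytokine genes fell (1 up and 15 down of 22, 1 and 16 adjusted over the list alone, median -1.13). For that list, camera gave adjusted p = 3.13e-11 (0.035 with an estimated correlation), so the call held. The efflux pump ABCG2 rose to 15.9 ± 3.10 TPM against 1.38 ± 0.170 TPM (log2 2.82, adjusted p = 8.02e-07), with UCA1 (log2 2.58, SE 0.19), H4C8 (2.93, SE 0.41) and H2BC4 (2.67, SE 0.57). H4C12 was listed at 0 in DMSO and RN7SL657P after withdrawal. BET markers and histone genes stayed higher (6 up and 1 down of 12, 8 and 1 adjusted over the list alone, median 1.24). DNA replication genes, lower on drug, were higher (11 of 23, 11 adjusted over the list alone, median 0.44), with RRM2 (log2 0.94, SE 0.21). Camera, in that order, gave adjusted p = 5.46e-07 and 4.68e-07 (0.083 and 0.257 with an estimated correlation). Cholesterol genes (16 of 24, 17 adjusted over the list alone, median -0.51) and fatty acid synthesis genes (7 of 11, 8 adjusted over the list alone, median -0.49) fell, with PCSK9 (log2 -2.03, SE 0.19) and SCD (-2.25, SE 0.12). The pair of tests gave adjusted p = 1.58e-08 and 2.34e-06 (0.106 and 0.0743 with an estimated correlation). BRD2 was higher (log2 0.49) and BRD4 lower (-0.41), but after scaling 4 drug target genes were higher and 0 lower. Limma called 1027 genes up and 2851 down, or 1954 and 2067 after scaling. The total of 3878 became 2577 and 2508 without DMSO replicates 1 and 2 and 2224 without withdrawn replicate 1. Against the on-drug group 2238 were higher and 648 lower, or 1384 and 1165 after scaling. That total of 2886 became 1806 and 1446 without withdrawn replicates 1 and 2. Of 1914 genes changed 2-fold or more on drug, 71.3% were still called the same way, 45.8% had moved back and the median share left was 60.2%, or 48.4% for the 270 that rose and 62.3% for the 1644 that fell.

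What did UNC1999 do to MDA-MB-231 in 72 h? Cholesterol genes rose (22 of 24, 23 adjusted over the list alone, median 1.44), led by HMGCS1 (log2 2.67, SE 0.16), MVD (2.20, SE 0.11), ACAT2 (2.05, SE 0.07) and DHCR7 (2.03, SE 0.12). Camera called them at adjusted p = 8.97e-52 (0.000977 with an estimated correlation). HMGCS1, which makes HMG-CoA, reached 275 ± 11.6 TPM against 42.6 ± 6.84 TPM (adjusted p = 2.32e-07). The cholesterol exporters ABCA1 and ABCG1 fell, to 2.45 ± 0.0424 TPM against 17.4 ± 0.318 TPM (log2 -2.42) and 0.655 ± 0.00707 TPM against 7.41 ± 0.0212 TPM (log2 -2.34). Lysosome genes rose (10 of 21, 11 adjusted over the list alone, median 0.31), with NEU1 (log2 0.93, SE 0.06) and SQSTM1 (0.81, SE 0.08). This test gave adjusted p = 3.68e-11 (0.0214 with an estimated correlation), so that call held. The cytokine IL24 (log2 2.72, SE 0.21), the prostaglandin synthase PTGS2 (2.20, SE 0.21) and the proton pump subunit ATP6V0D2 (2.23, SE 0.19) rose, and RAB17 (log2 -1.96, SE 0.20) and TGFB2-OT1 (-3.03, SE 0.63) fell. TFF1 (log2 -4.54, SE 0.84) and SPTSSB (log2 -3.30, SE 0.70) fell, and DSCAM-AS1 was listed at 0, with MCF7 shares of 261%, 147% and 187% of their changes. The pseudogene FGF7P5 was listed at 0 too, and its call and that of H4C12 were lost in the 34-library fit. RPL36A-HNRNPH2, H4C12 and RN7SL4P, listed at 0 in DMSO, can share reads with other genes. No drug target gene was called. Limma called 547 genes up and 554 down, or 659 and 472 after scaling. The total of 1101 became 512 and 336 without DMSO replicates 1 and 2, and 314 and 607 without UNC1999 replicates 1 and 2.

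What stood apart from DMSO 72 h after UNC1999? CHI3L2 (log2 3.93, SE 0.27) and the serpin SERPINB4 (log2 3.27, SE 0.17) rose, CHI3L2 to 92.4 ± 29.5 TPM against 5.09 ± 1.66 TPM (adjusted p = 4.44e-07). The NF-kB and cytokine genes rose (14 up and 2 down of 22, 16 and 2 adjusted over the list alone, median 0.77), with CCL20 (log2 2.68, SE 0.31), IL1B (2.54, SE 0.18), IL1A (2.27, SE 0.19) and CXCL8 (1.98, SE 0.12). Camera gave adjusted p = 1.61e-10 (0.035 with an estimated correlation), so the call held. DNA replication genes (20 of 23, 21 adjusted over the list alone, median -0.75) and mitosis genes (15 of 20, 16 adjusted over the list alone, median -0.54) fell, with TYMS (log2 -1.28, SE 0.13) and CCNA2 (-0.95, SE 0.13). Camera tests gave adjusted p = 1.64e-13 and 4.8e-08 (0.133 and 0.245 with an estimated correlation). Mitochondrially encoded genes fell, to 21.28% of TPM against 25.49% in DMSO (9 of 13, 11 adjusted over the list alone, median -0.28), with 4 called after scaling. Its camera test gave adjusted p = 7.87e-05 (0.252 with an estimated correlation). Matrix genes (8 up and 1 down of 19, 10 and 1 adjusted over the list alone, median 0.48) and the unfolded protein response (7 of 15, 10 adjusted over the list alone, median 0.34) rose, with FN1 (log2 2.31, SE 0.12) and HYOU1 (0.64, SE 0.08). Their camera tests gave adjusted p = 4.78e-06 and 3.42e-06 (0.0949 and 0.128 with an estimated correlation). Drug target genes were called lower (4 of 9, 6 adjusted over the list alone, median -0.39), with EP300 (log2 -0.80, SE 0.21), SUZ12 (-0.68, SE 0.17), EZH2 (-0.39, SE 0.12) and BRD2 (-0.24, SE 0.07), and after scaling 2 were called lower. The camera test gave adjusted p = 0.00798 (0.196 with an estimated correlation). SPTSSB (log2 -3.39, SE 0.70) fell and DSCAM-AS1 was listed at 0, with MCF7 shares of 128% and 163% of their changes. FAUP4 and RPS28P4, listed at 0 in DMSO, are pseudogenes whose calls were lost with no filter. H4C12 was listed at 0 in DMSO, and the pseudogenes RN7SL657P, RPL32P29 and FGF7P5 after withdrawal. Limma called 1488 genes up and 1981 down, or 1869 and 1421 after scaling. The total of 3469 became 1664 without DMSO replicate 2 and 1954 without withdrawn replicate 2. Against the on-drug group 1588 were higher and 1954 lower, or 1843 and 1644 after scaling. That total of 3542 became 2147 and 2084 without on-drug replicates 1 and 2 and 1887 without withdrawn replicate 2. Of 173 genes changed 2-fold or more on drug, 44.5% were still called the same way, 50.9% had moved back and the median share left was 44.3% (33.7% for the 100 that rose, 55.9% for the 73 that fell), or 16.9% and 26.5% without on-drug replicates 1 and 2. Of 488 genes changed 2-fold or more after withdrawal, 398 had not been called on drug.

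Did the 2 EZH2 inhibitors, both at 5 µM, differ? UNC1999 raised cholesterol genes further than GSK126 (19 of 24, 20 adjusted over the list alone, median 0.89), as in HMGCS1 (log2 1.73, SE 0.16) and MVD (1.48, SE 0.11). Camera called the difference at adjusted p = 4.03e-59 (0.000439 with an estimated correlation). The exporters ABCA1 (2.45 ± 0.0424 TPM against 16.2 ± 0.255 TPM, log2 -2.32, adjusted p = 9.55e-06) and ABCG1 (log2 -1.97, SE 0.20) were lower on UNC1999. PTGS2 (log2 2.17, SE 0.21), IL24 (2.09, SE 0.21) and ATP6V0D2 (1.48, SE 0.19) were higher, while KDM5A (log2 -1.37, SE 0.17), ID3 (-1.42, SE 0.25) and NDUFA3 (-1.32, SE 0.19) were lower. Lysosome genes were higher (3 of 21, 6 adjusted over the list alone, median 0.11), with NEU1 (log2 0.57, SE 0.06). Tested by camera, it had adjusted p = 2.74e-09 (0.0535 with an estimated correlation). EZH2 did not differ by a called amount (log2 -0.23, 95% interval -0.49 to 0.02). Of 16329 genes 57 were higher and 38 lower, or 60 and 22 after scaling. The total of 95 became 40 and 49 without GSK126 replicates 1 and 2, and 42 and 49 without UNC1999 replicates 1 and 2.

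After withdrawal the 2 EZH2 inhibitors differed in division and growth signal genes. DNA replication genes were higher after UNC1999 than after GSK126 (13 of 23, 19 adjusted over the list alone, median 0.63), and AP-1 and ERK output was lower (1 up and 8 down of 19, 1 and 9 adjusted over the list alone, median -0.54). Examples were E2F1 (log2 0.92, SE 0.12), MCM5 (0.88, SE 0.11), EGR1 (-1.87, SE 0.43) and DUSP5 (-1.34, SE 0.15). For these lists, camera gave adjusted p = 6.09e-15 and 2.23e-08 (0.138 and 0.16 with an estimated correlation). The growth factor AREG stood at 353 ± 44.8 TPM against 1062 ± 307 TPM (log2 -1.56, adjusted p = 0.000464). ZNF774 (log2 2.66, SE 0.37), SLC38A9 (1.64, SE 0.27), BAZ2B (1.60, SE 0.26) and KIF20B (1.57, SE 0.24) were higher and TSGA10 (log2 -2.36, SE 0.53) and LINC01943 (-1.62, SE 0.34) were lower, the latter a call lost with a pseudocount of 0.1. EXOC6 (log2 3.11, SE 0.71) was higher and ACAP1 (log2 -2.46, SE 0.66) lower, calls lost with no filter. EZH2 was higher (log2 0.50) and BRD2 lower (-0.27). Called were 597 genes higher and 284 lower, or 433 and 667 after scaling. The total of 881 became 102 without GSK126 withdrawn replicate 2, 197 without UNC1999 withdrawn replicate 1 and 510 without UNC1999 withdrawn replicate 2.

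How did the 2 p300 and CBP inhibitors differ in MDA-MB-231, given 5 µM of A485 and 10 µM of CCS1477? Scaling moved the all-gene median by -0.349, so list medians are relative to the measured median of 0.343. Fatty acid synthesis genes were lower on A485 (9 of 11, 9 adjusted over the list alone, median -1.15), as in SCD (log2 -3.96, SE 0.12), SREBF1 (-2.50, SE 0.13) and FASN (-2.45, SE 0.13). Camera called the difference at adjusted p = 7.16e-10 (0.0232 with an estimated correlation). Cholesterol genes (3 up and 12 down of 24, 3 and 13 adjusted over the list alone, median -0.70) and hypoxia and glycolysis genes (2 up and 11 down of 18, 2 and 12 adjusted over the list alone, median -0.98) were lower, with INSIG1 (log2 -2.78, SE 0.15) and ENO1 (-1.92, SE 0.09). Tested by camera, they had adjusted p = 2.25e-07 and 1.21e-07 (0.139 and 0.24 with an estimated correlation). SPINK4 was listed at 0 on A485, and LIPG (log2 -4.61, SE 0.19), KRT7 (-4.57, SE 0.19), ID1 (-4.57, SE 0.18) and KRT80 (-4.45, SE 0.11) were lower. The adhesion gene ICAM1 stood at 796 ± 21.6 TPM against 96.5 ± 5.08 TPM (log2 3.03, adjusted p = 2.15e-12), and IL27RA (log2 3.65, SE 0.14), TFPI (3.38, SE 0.21) and EGR1 (3.42, SE 0.43) were higher, with KRT8P51, listed at 0 on CCS1477. EED (log2 1.01), SUZ12 (0.98), EZH2 (0.86), BRD4 (0.65) and EP300 (0.63) were higher and BRD2 lower (-0.42), but after scaling 3 drug target genes were higher and 2 lower. Called were 7027 genes higher and 1495 lower, or 2480 and 3182 after scaling.

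After withdrawal the 2 p300 and CBP inhibitors differed less. ANGPTL4 was lower after A485 than after CCS1477 (log2 -3.49, adjusted p = 2.57e-06), as were IL11 (log2 -2.41, SE 0.21), LTB (-1.99, SE 0.30), UCA1 (-1.89, SE 0.19) and CSF2 (-1.38, SE 0.21). ALOX5AP (log2 3.39, SE 0.30), ITGB2 (2.82, SE 0.25) and PCBP1-AS1 (2.78, SE 0.26) were higher. So were WT1 (log2 2.73, SE 0.65) and BRICD5 (log2 3.16, SE 0.90), calls lost without the 2 libraries richest in other-line transcripts. DNA replication genes (8 of 23, 14 adjusted over the list alone, median -0.36) and mitosis genes (3 of 20, 7 adjusted over the list alone, median -0.31) were lower, with E2F1 (log2 -0.75, SE 0.12) and CCNB1 (-0.43, SE 0.08). In that order, camera gave adjusted p = 1.01e-11 and 2.61e-07 (0.192 and 0.29 with an estimated correlation). Matrix genes (6 up and 1 down of 19, 13 and 1 adjusted over the list alone, median 0.66) and fatty acid synthesis genes (5 up and 0 down of 11, 7 and 1 adjusted over the list alone, median 0.36) were higher, with TNC (log2 2.11, SE 0.59), VIM (1.19, SE 0.06) and SCD (1.63, SE 0.12). The 2 tests gave adjusted p = 1.27e-05 and 2.86e-05 (0.117 and 0.117 with an estimated correlation). Other-line shares were 82% of the change of TNC, 72.8% of COL4A1, 51.8% of TGFBI, 86.8% of ACSL3 and 51.6% of FASN, and both list calls held without those 2 libraries. EP300 did not differ by a called amount (log2 -0.50, 95% interval -0.95 to -0.05). Called were 977 genes higher and 316 lower, or 693 and 643 after scaling. The total of 1293 became 532 and 524 without CCS1477 withdrawn replicates 1 and 2.

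Did CCS1477 act differently in MCF7 and in MDA-MB-231? Values are MCF7 (EMEM) minus MDA-MB-231 (DMEM) changes, over 13725 genes tested in both, so line and medium were confounded. Mitosis genes (16 of 20, 17 adjusted over the list alone, median -1.23) and MYC and its targets (17 of 24, 20 adjusted over the list alone, median -0.68) were lower in MCF7, with AURKB (log2 -2.71, SE 0.24) and NME1 (-1.44, SE 0.15). Both camera tests gave adjusted p = 1.65e-12 and 5.84e-08 (0.139 and 0.197 with an estimated correlation). SLC7A5 (log2 -3.35, SE 0.17) and AREG (-3.53, SE 0.21) were lower in MCF7, and CSF2 (log2 4.52, SE 0.29) and IL6 (4.05, SE 0.49) higher. CSF2 rose by 1.28 in MCF7, with an MDA-MB-231 share of 149%. Cytokine and NF-kB genes (8 up and 3 down of 15, 8 and 4 adjusted over the list alone, median 1.41) differed as a list. For that list, camera gave adjusted p = 0.03 (0.229 with an estimated correlation), a call lost with a pseudocount of 0.1. S100A14 (log2 -5.61, SE 0.46) (adjusted p = 1.59e-07), AKR1C2 (-4.29, SE 0.64), AGR3 (-4.23, SE 0.71) and KRT81 (-4.22, SE 0.19) were lower in MCF7. SAA1 (log2 6.12, SE 0.91), CST1 (6.09, SE 0.60) and SAA2 (5.41, SE 0.71) were higher. Their MDA-MB-231 shares were 87%, 122% and 94.9% of the changes in MCF7. Called were 1820 genes higher and 2077 lower, or 2113 and 2078 after scaling. Without shared controls, the changes in the 2 lines correlated at r = 0.34, with 711 genes up and 1137 down in both, against 335.7 and 555.1 for independent lists, and at r = 0.24 after withdrawal.

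After withdrawal the 2 lines, in different media, differed in stress and lipid genes. ATF4 genes (15 of 19, 16 adjusted over the list alone, median -1.47) and the unfolded protein response (12 of 15, 13 adjusted over the list alone, median -1.12) were lower in MCF7, with SLC3A2 (log2 -2.54, SE 0.18) and HSPA5 (-1.76, SE 0.17). Camera, in that order, gave adjusted p = 1.65e-12 and 1.65e-12 (0.117 and 0.0824 with an estimated correlation). Cholesterol genes (19 of 23, 20 adjusted over the list alone, median 0.88) and fatty acid synthesis genes (6 up and 1 down of 11, 6 and 1 adjusted over the list alone, median 0.71) were higher in MCF7, with INSIG1 (log2 3.76, SE 0.20) and SCD (2.96, SE 0.18). The pair of tests gave adjusted p = 1.01e-11 and 0.000739 (0.117 and 0.24 with an estimated correlation). NF-kB and cytokine genes were lower (0 up and 8 down of 15, 1 and 10 adjusted over the list alone, median -0.93), with IL11 (log2 -2.82, SE 0.34) and LIF (-2.07, SE 0.26). This test gave adjusted p = 9.64e-06 (0.0232 with an estimated correlation), so the call held. CYP1A1 (log2 -4.88, SE 0.45), ANGPTL4 (-3.92, SE 0.33), NAV2 (-3.77, SE 0.24) and DHRS2 (-3.77, SE 0.34) were lower in MCF7 and NPNT (log2 3.88, SE 0.52) was higher (adjusted p = 3.33e-05). CST4, listed at 0 in MCF7 DMSO, and CST1 had MDA-MB-231 shares of 152% and 173%. SUZ12 (log2 0.77) and BRD2 (0.45) were higher in MCF7. Developmental regulators, with 4 measured in both lines, were not tested. Called were 2179 genes higher and 1603 lower, or 1979 and 1984 after scaling.

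Correlations here are across genes, which are not independent replicates. Arms that share a DMSO group correlate through it, so each pair was set against 20 simulated sets of unchanged groups with the same shared control, which had r = 0.49 to 0.5. On drug in MDA-MB-231, CCS1477 and OTX-015 had r = 0.74 and a covariance of 0.301, against 0.041 simulated. They shared 1011 genes up and 2654 down, against 191.8 and 1007 for independent lists, and had r = 0.55 after withdrawal. A485 and CCS1477 had r = 0.54 on drug and a covariance of 0.249 against 0.043, with 1490 genes up and 1215 down, against 832.2 and 391.1, and 783 opposite. After withdrawal they had r = 0.67, with 1502 up and 979 down, against 334.6 and 179.1, and 34 opposite. On drug GSK126 and UNC1999 had r = 0.66, a covariance of 0.0982 against 0.041, and 105 genes up and 40 down, against 4.221 and 1.561. After withdrawal GSK126 and UNC1999 had r = 0.77, a covariance of 0.237 against 0.042, and 1238 up and 1726 down, against 214.1 and 485.4. With no shared control, I-BET151 in A375 and OTX-015 in MDA-MB-231 had r = 0.45, with 696 genes up and 1854 down in both, against 201.9 and 980.4. After withdrawal they had r = 0.14, with 21 up and 180 down, against 16.59 and 94.76.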

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

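All tests in this part but those of differences between the 2 lines and the scaling were chosen after the results were seen. The changes on CCS1477 differed between MCF7 and MDA-MB-231 when tested directly for 3897 genes on drug and 3782 after withdrawal. Values below are log2, MCF7 (EMEM) minus MDA-MB-231 (DMEM). On drug they were 6.35 for RMRP, 6.12 for SAA1, 6.09 for CST1, 5.41 for SAA2 and 5.18 for SRP9P1, and -5.61 for S100A14, -4.29 for AKR1C2, -4.23 for AGR3, -4.22 for KRT81 and -4.08 for LINC01522. RMRP stood at 10.65 ± 15.1 TPM in MCF7 on drug (n = 2). MDA-MB-231 transcripts equalled 87% and 94.9% of the MCF7 changes of the markers SAA1 and SAA2, and 122% for CST1. After withdrawal they were 7.57 for RMRP, 5.16 for SRP9P1, 5.01 for CST1, 4.01 for CST4 and 3.88 for NPNT, and -4.88 for CYP1A1, -4.32 for S100A14, -3.92 for ANGPTL4, -3.77 for NAV2 and -3.77 for DHRS2, with MDA-MB-231 shares of 173% for CST1 and 152% for CST4.

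Median gene differences of the lists on drug were -0.68 for MYC targets, -0.68 for DNA replication, -1.23 for mitosis, 0.60 for MHC class I, 0.83 for MHC class II, 1.41 for NF-kB and cytokines, 0.36 for lysosome, -0.54 for ATF4, -0.42 for the unfolded protein response, -0.70 for AP-1, 0.75 for YAP targets and 0.27 for mitochondrially encoded genes. After withdrawal they were -0.69 for MYC targets, 0.47 for DNA replication, 0.73 for mitosis, 0.48 for MHC class I, -0.93 for NF-kB and cytokines, 0.55 for matrix, 0.88 for cholesterol, 0.71 for fatty acid synthesis, 0.26 for lysosome, -1.47 for ATF4, -1.12 for the unfolded protein response, -0.30 for AP-1 and 0.66 for YAP targets. With an estimated correlation none of the on-drug calls held (adjusted p = 0.139 to 0.611), and after withdrawal NF-kB and cytokines did (adjusted p = 0.0232) and the others did not (0.0824 to 0.497). In MCF7 other-line shares were 41.4% to 118% for the YAP targets F3, CCN2, CCN1 and ANKRD1 on drug. They were 64.9% and 57.8% for CCN1 and ANKRD1 after withdrawal.

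More genes were called after withdrawal of GSK126 and UNC1999 than on them. If longer culture changed every withdrawn group alike, their log2 changes would covary with those of the other 3 withdrawn arms beyond the shared DMSO libraries, and the 6 covariances beyond the simulated ones were -0.0519 to -0.00772, against 0.196 (0.186 to 0.205 from single libraries) between GSK126 and UNC1999. The 24 single-library values ran from -0.0561 to 0.00327, so the bound of 0 was not passed by all. Opposite drug effects could offset a shared effect of time. Other-line transcripts of the DMSO libraries, absent from the simulation, could add to the covariances. This test had 4 forms, all written after values were seen; one that would have excluded longer culture loosened the bound afterwards and was dropped, so longer culture, which is confounded with withdrawal, stays open. Removal of the drug (untested), exchanged labels and denser cultures stay open as well: developmental regulators changed from on drug to withdrawn by medians of 0.56 in GSK126 and 0.32 in UNC1999 (unadjusted camera p = 0.0291 and 0.0777 with an estimated correlation), and YAP targets stood at -0.01 and -0.18 against DMSO (camera adjusted p = 0.3 and 0.97).

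Single libraries held transcripts of another line. In the A485 withdrawn replicate 1 library 97.7% of A375 markers (43 of 44) stood within 2 times of their median of 19.2%, and in OTX-015 replicate 2 this held for 89.5% of MCF7 markers (17 of 19) around 9.29%, which is what RNA or reads of these lines would give. Induction by the treatment would give like levels in both replicates, yet the other replicate had a ratio of 0.0022 for A375 markers and 0.18 for MCF7 markers. Whether cells, RNA, libraries or reads were mixed cannot be told apart from TPM, and no biological explanation beyond induction was tested.

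On A485 more genes were higher than lower. A loss of mitochondrial transcripts would raise all other TPM values, but without mitochondrially encoded genes the median change of all genes was 0.241, against 0.311 with them, so this was not the whole cause. A shift common to most genes stays open, since median-ratio scaling, which centres the genes by construction, brought the calls that were higher to 44.3%, and TPM hold no outside standard. An effect of A485 itself stays open too, untested.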

How the results depend on the processing

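Of the alternatives, the fits without mitochondrially encoded genes, without genes at least 10 times higher in another line and without the 2 libraries richest in other-line transcripts were chosen after the results were seen. No named gene or share left changed sign under the alternatives run, no correlation did with scaling, and no called list was called the other way. The medians of 124 list results, 13 of them called, changed sign under at least 1 alternative. Scaling did so for 43, and changed which side was larger in 15 counts of genes. All 27 counts of called genes stayed within 1.5 times with a pseudocount of 0.1 and without mitochondrially encoded genes, as did the 25 that could be counted without genes higher in another line. What sequencing depth limited is unknown, because TPM hold no read numbers.

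Leaving out 1 library moved 52 counts beyond 1.5 times and left 64 within. The lone library left in a group was then assumed to vary like the other groups. Ranges against DMSO on drug were 3258 to 3857 for A375 (5437 with all libraries), 3046 to 4944 for MCF7 (5850), 12 to 22 for GSK126 (172) and 314 to 607 for UNC1999 (1101). After withdrawal they were 103 to 225 for A375 (841), 1791 to 3357 for MCF7 (3969), 1701 to 3248 for A485 (3308), 3208 to 3723 for CCS1477 in MDA-MB-231 (5074), 4153 to 5098 for GSK126 (6351), 2224 to 2686 for OTX-015 (3878) and 1664 to 2380 for UNC1999 (3469). Withdrawn against on drug gave 2528 to 2751 for A375 (4741), 1280 to 2053 for MCF7 (3789), 3028 to 3364 for CCS1477 in MDA-MB-231 (4689), 1446 to 2537 for OTX-015 (2886) and 1887 to 2567 for UNC1999 (3542). UNC1999 against GSK126 gave 40 to 49 on drug (95) and 102 to 615 withdrawn (881), and A485 against CCS1477 withdrawn 524 to 1359 (1293). The counts of A485, OTX-015 and CCS1477 on drug in MDA-MB-231, of withdrawn against on-drug A485 and GSK126, of A485 against CCS1477 on drug, and of MCF7 against MDA-MB-231 stayed within 1.5 times.

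Shares of the change left ranged without 1 library from 19.3% to 26.3% for A375 (21%), 49.8% to 59% for MCF7 (53.9%), 27.5% to 34.1% for A485 (29.6%), 49.4% to 59.1% for CCS1477 in MDA-MB-231 (54.7%), 33.8% to 96.5% for GSK126 (81.6%), 54.2% to 63.1% for OTX-015 (60.2%) and 16.9% to 55.4% for UNC1999 (44.3%). With the DMSO libraries split they moved to 19.2% and 23.7% for A375, 41.8% and 40% for UNC1999 and 72% for GSK126. Genes changed 4-fold gave 57.9% for MCF7, 25.1% for A485, 100% for GSK126, 65.2% for OTX-015 and 47% for UNC1999. Scaling gave 19.4% for A375, 32.1% for A485, 76.1% for GSK126 and 40.9% for UNC1999. A pseudocount of 0.1 gave 89% for GSK126 and 41% for UNC1999, the fit of all 34 libraries 74.6% and 42.6%, and no filter 31.1% for UNC1999.

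Other counts that moved were those of withdrawn A375 without a filter (425) and with a replicate block (421), of MCF7 withdrawn against on drug without a filter (2337), and of MCF7 withdrawn against DMSO and on drug in the fit of all 34 libraries (5954 and 5827). A485 against CCS1477 on drug gave 5662 after scaling, and GSK126 on drug 399 without the 2 libraries richest in other-line transcripts. Scaling moved the correlations on drug of CCS1477 with OTX-015 to 0.73 and of OTX-015 with UNC1999 to 0.15. For the moved results of this part the cause was not tested. Replicate numbers did not mark pairs of libraries: correlations of the replicate difference between groups lay from -0.09 to 0.09 over 55 pairs of MDA-MB-231 groups, from -0.07 to 0.04 in A375 and from -0.07 to -0.01 in MCF7.

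Of the 242 named genes, calls lost were 4 with scaling, 24 without a filter, 13 in the fit of all 34 libraries, 15 with a pseudocount of 0.1, 6 with a replicate block, 2 without mitochondrially encoded genes, 3 without the 2 libraries, 0 of the 197 left without genes higher in another line, and 182 over all refits that left out 1 library. Camera called 247 of 518 list results. With an estimated correlation 235 lost the call and 12 held. Calls lost were 11 with scaling, 7 without a filter, 11 in the fit of all 34 libraries, 2 with a pseudocount of 0.1, 11 without genes higher in another line, 3 without mitochondrially encoded genes, 8 without the 2 libraries, 0 with the block. Refits that left out 1 library lost 74 list calls and gained 64.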

Other observations

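As measured, MHC class II genes were lower on CCS1477 in MDA-MB-231 (8 of 12, median -1.25), with CIITA (log2 -2.17) and HLA-DRA (log2 -2.43). They stayed below DMSO after withdrawal of CCS1477 (8 of 12, median -0.95) and of OTX-015 (9 of 12, median -1.32). Camera gave adjusted p = 0.000155, 0.000234 and 1.26e-05 (0.329, 0.257 and 0.197 with an estimated correlation). These genes and this list were picked after their values were seen.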
